A study of Mus musculus with 11 samples.

How the data were processed

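Basal ganglia of wild-type CD1 mouse embryos at E13.5 were dissected, fixed with formaldehyde and used for ChIP, per the labels' protocols, and the tissue held the progenitor and mantle zones of the LGE, MGE and CGE. Per the same protocols, the ARX chromatin was fixed with more formaldehyde and for longer than that of SP9, ASCL1, GSX2 and NR2F1. The series held 11 samples: 5 ChIP samples, 5 inputs without files of their own and 1 H3K4me3 PLAC-seq sample. The peak lists of DLX1, DLX2, DLX5, LHX6, NKX2.1, OTX2 and PBX1 accompanied the whole series, so their factor, control and depth were taken from the list headers. The design text of the series states that the peak files include data of other series, without naming the lists. Per the file headers, the ARX control was a merged input, and the ASCL1 library name includes the crosslinker DSG, which the labels' protocols do not mention.

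Single-end reads were trimmed with Trim Galore 0.4.5, aligned with BWA 0.7.9a and handled with SAMtools 1.8 against mm10, per the submitters' processing notes for the samples; for the 7 lists of the whole series only the trimming and alignment by bwa that their headers name are known. Peaks were called with MACS2, given as 2.1 in the submitters' processing notes and as 2.1.2 in the list headers. Per the file headers, each library was called against its input with a p cutoff of 0.0001, no local background, no fragment model, a fragment length of 200 bp and summit calling. The fold enrichment is a ratio made by the authors, the ChIP pileup at the summit over the control, with the larger library scaled to the smaller. The -log10 p and -log10 q values are the authors' deposited values per peak; the headers state that q was not calculated, but the columns are present. In each of the 12 lists every fold value went with exactly 1 p value, and the background of the 5 lists of samples, checked from pileup and fold, was constant (from 1.13 for ARX to 2.43 for GSX2). The input therefore did not act locally, and signal that is also high in the input was not removed by the caller.

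The contact list gives pairs of 10 kb bins on the autosomes. Its counts are deposited read counts per pair of bins, without normalization. The expected value beside each count comes from the authors' model, and the false discovery rate is a p-value adjusted by the authors. The tool that called the contacts is not given in the sources used here. The values held no count under 12, no observed over expected value under 2.00 and no false discovery rate above 0.0100, as checked on the list. The list combines the runs named in its label, and runs could not be separated.

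Peaks on chromosomes 1 to 19, X and Y were kept, and 44 mitochondrial intervals were left out. Summits of 1 interval were collapsed to the most significant. The pileup columns of the 7 lists of the whole series were not used here. Genes were the 21883 protein-coding genes of the RefSeq table for GRCm38, the assembly of mm10. The table gives no strand, so start sites could not be placed. A promoter was replaced by the 1000 bp around either boundary of a gene, and the nearest start site by the nearest gene span within 100 kb; these are deviations from the plan. Motif searches and their 4 alternatives were not run because they need the genome sequence, which was not used here.

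Boundary-proximal shares were given with exact binomial 95% intervals (Clopper-Pearson) and with the share of peaks shifted along the chromosome. Overlap of list pairs (1 bp or more) was divided by its mean over 100 seeded circular shifts of at least 1000000 bp along each chromosome. Overlapping peaks of all lists were merged to regions, and a region of 6 or more factors was called highly shared. Hotspots are regions that all 12 lists hold with 20 kb to each side. Regions were placed in contact bins by their summit and compared with shifted regions. Contacts with a mark in both bins were compared with 100 permutations of the far bins among contacts of the same distance. A gene list's mean number of factors and of distal regions was set against 10000 random lists of the same size, matched on the decile of the territory around a gene, or on the decile of the number of contacts for linked regions. With 1 library per factor no test between factors was possible, and percentiles describe these libraries. The correlation of depth with peak number was the only relation tested across lists, with 100000 permutations for 10 or more lists and exact enumeration for 7 and 5.

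The 15 gene lists, the named items and all alternatives in the plan were fixed before the data were examined. The lists held 201 entries for 178 different genes, so some genes count in several lists. Named were the profiled factor genes with their Dlx neighbours, up to 4 genes per list with the most factors and those with none, the 20 genes with the most linked distal regions of 6 or more factors, the 10 regions with the most factors ranked by mean significance within lists, and the 3 most significant peaks per list. Alternatives covered stricter significance or fold, other distances, other overlap definitions, lists of equal size, leaving out each list, other limits of shared factors, stricter or longer contacts and unmatched random lists. Those that left out hotspots or wide peaks, and the bin on the other side as a chance level, also when weighted by number of contacts, as well as gene lists without each of their genes, were added after the data were seen.

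The overlap, list and contact steps were tested on simulated data. Of 800 shared peaks planted in lists of 4000 and 6000, 797.4 were found beyond the shifted mean. Of 200 random gene lists, 4% lay above the 95th percentile. Random marks gave a contact ratio with a mean of 1.02 (0.88 to 1.28 over 20 sets) and marks planted at linked bins gave 4.43. The random marks were placed bin by bin, so the simulation did not cover neighbouring bins that are marked together. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.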

Results

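The series measured transcription factor binding and promoter contacts in the basal ganglia of wild-type CD1 mouse embryos at E13.5. This ventral forebrain tissue comprises the lateral, medial and caudal ganglionic eminences (LGE, MGE and CGE), which give rise to striatal projection neurons and to inhibitory interneurons. Binding was given as 12 lists of ChIP-seq peaks. The lists of ARX, ASCL1, GSX2, NR2F1 and SP9 belonged to 5 ChIP samples of the series. The lists of DLX1, DLX2, DLX5, LHX6, NKX2.1, OTX2 and PBX1 accompanied the series as a whole, and their factor was read from the header of each list. Contacts came from H3K4me3 PLAC-seq, which captures ligated pairs of distant fragments where DNA carries this mark of active promoters. The remaining 5 of the 11 samples were inputs without files of their own. Each factor had 1 library, so there were no replicates and no spread between libraries; intervals below cover counting error only. The ChIP tags kept by the peak caller numbered 10557366 for ARX, 15702085 for ASCL1, 17778326 for DLX1, 31048385 for DLX2, 35104599 for DLX5, 22676429 for GSX2, 21689355 for LHX6, 21010443 for NKX2.1, 20895498 for NR2F1, 20367007 for OTX2, 41224665 for PBX1 and 16220734 for SP9. Input tags kept ranged from 14992949 for NR2F1 to 126555856 for ARX.

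The number of peaks per list described how widely each factor was found. DLX2, a homeodomain factor of subpallial GABAergic neurons, had 17178 peaks, the most of the 12 lists. SP9, a zinc finger factor of striatal and interneuron precursors, had 7541. NKX2.1, which specifies the MGE, had 6761 peaks and its target LHX6, a LIM homeodomain factor of MGE-derived interneurons, had 1750. DLX1 had 6308 peaks, DLX5 4493, GSX2 4441, ARX 4245, PBX1 3705 and OTX2 2123. ASCL1, the proneural bHLH factor of ventral progenitors, had 1540, and the orphan nuclear receptor NR2F1 had 865. The lists together held 60950 peaks on 21 chromosomes. The order of lists depended on the threshold: a minimum fold of 5.0 left 5005 peaks of SP9, 3536 of ARX, 2515 of GSX2, 1944 of DLX5, 1410 of PBX1, 1047 of OTX2 and 949 of ASCL1, and a minimum -log10 q of 5.0 left 4429 of SP9, 2903 of GSX2, 2774 of DLX5, 2567 of ARX, 886 of OTX2, 801 of ASCL1 and 532 of NR2F1.

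The peaks with the highest significance in each list were mostly common to all 12 lists, and whether they reflect binding is taken up below. Of the 36 peaks formed by the 3 most significant peaks of every list, 31 lay in regions that all 12 lists held. The region on chromosome 9 from 35305062 to 35305659 (mm10), 29412 bp from Rpusd4, was among the 3 in all lists except DLX1 and was the most significant peak of ARX, with a fold enrichment of 82.7 in the authors' deposited table. The 5 exceptions were 3 DLX1 peaks, 1 DLX2 peak and 1 SP9 peak. In the authors' deposited table, the DLX1 peaks lay inside Oxsr1 (chromosome 9, 119322305 to 119323031, fold 105), Lemd2 (chromosome 17, 27204171 to 27205186, fold 103) and Fbxo38 (chromosome 18, 62548404 to 62549053, fold 96.9). The DLX2 peak inside Adk, which encodes adenosine kinase, spanned 21251760 to 21253028 on chromosome 14 and had a fold of 46.8 in the same table. The SP9 peak inside Auts2, a gene linked to neurodevelopmental disorders, spanned 131869543 to 131870282 on chromosome 5 with a fold of 73.1 in the authors' deposited table. Peak number was not related to depth in a way the lists could show: across the 12 lists Pearson's r was 0.229 (two-sided permutation p = 0.439) and Spearman's rho 0.161 (permutation p = 0.620). Single lists carried much of r, which was -0.0604 without DLX2 (p = 0.872) and 0.394 without PBX1 (p = 0.273), and rho was -0.00909 without ASCL1 and 0.00909 without DLX2. Without the 2 lists farthest from the median depth, r was 0.579 (permutation p = 0.133), and it was 0.147 among the 7 lists of the whole series (exact permutation p = 0.724) and -0.208 among the 5 lists of samples (exact permutation p = 0.75). A minimum fold of 5.0 left 40592 peaks, and only the top peaks named here carry per-peak values of the authors.

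The location of peaks relative to genes separated the factors into groups. NR2F1 had 23.4% of its peaks within 1000 bp of a boundary of a protein-coding gene (exact 95% interval 20.6 to 26.3), and PBX1, a TALE homeodomain cofactor, had 19.0% (17.7 to 20.3). NKX2.1 had 17.1% (16.2 to 18.0), SP9 16.8% (16.0 to 17.7), ASCL1 16.6% (14.8 to 18.6), DLX2 14.9% (14.3 to 15.4) and DLX1 8.43% (7.76 to 9.15). For the homeodomain factors LHX6, ARX, DLX5, GSX2 and OTX2 the share was 2.29% (1.64 to 3.10), 3.16% (2.65 to 3.73), 3.23% (2.73 to 3.79), 3.67% (3.14 to 4.27) and 3.67% (2.91 to 4.56). Peaks shifted along their chromosomes had shares from 3.02% for DLX5 and LHX6 to 3.32% for NR2F1. The enrichment over shifted peaks was 7.04 for NR2F1, 6.26 for PBX1 and 4.85 for DLX2, and it was 0.757 for LHX6, 1.03 for ARX and 1.07 for DLX5. The gene table held no strand, so a boundary is either end of a gene. Among the 865 most significant peaks of each list, which are all peaks of NR2F1, the share was 35.8% for PBX1, 10.5% for NKX2.1 and 2.43% (1.51 to 3.69) for DLX2, whose enrichment was lost (0.784, with the shifted share of 3.10% inside the interval). Top peaks of SP9, DLX5, ARX and LHX6 lay near boundaries less often than shifted ones, as 1.62% for SP9 (0.888 to 2.70), with ratios of 0.516, 0.630, 0.507 and 0.415, of which that of DLX5 had the shifted share of 3.12% inside its interval.

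The overlap of each pair of lists addressed which factors had peaks at the same sites. Each list came from a separate library of tissue that mixes many cell types, so factors at a shared site need not bind it in the same cell. LHX6 and ARX, both factors of migrating interneurons, had the highest enrichment of the 66 pairs when all peaks were used: 1132 of the LHX6 peaks (64.7%) overlapped an ARX peak, 488 times the mean of shifted lists. OTX2, a homeodomain factor of ventral progenitors and choroid plexus, and GSX2, a determinant of LGE progenitors, shared 1326 peaks (62.5% of OTX2), at 467 times the shifted mean. LHX6 and DLX5 shared 1056 peaks at 453 times that mean, and ARX and DLX5 shared 2480 at 450.1 times. The long DLX2 list held most peaks of several others, with 86.4% of ARX peaks, 84.0% of DLX5 peaks, 75.9% of GSX2 peaks and 75.8% of LHX6 peaks. NKX2.1 peaks overlapped 992 LHX6 peaks (56.7%).

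NR2F1 and DLX2 had the lowest enrichment, 51.7, with 244 NR2F1 peaks (28.2%) in the DLX2 list, and NR2F1 with SP9 had 85.6. All 66 pairs lay above each of the 100 shifts, with a median ratio of 222. With hotspots left out, meaning peaks within 20 kb of a region held by all 12 lists, all 66 pairs were still above each shift, the median was 213 and the NR2F1 and DLX2 ratio was 41.3. Circular shifts place peaks anywhere on a chromosome and do not account for where chromatin is open, so the ratios measure overlap against the whole chromosome. The length of the lists also limits the ratio, since a longer list raises the shifted mean. ARX with DLX2 had a ratio of 170 although 86.4% of the ARX peaks overlapped, so low ratios with DLX2 need not mean little overlap. With the 865 most significant peaks of every list, the median was 473.7 and the order changed, with LHX6 and ARX in place 6 and OTX2 and GSX2 in place 15 of the 66 pairs, and with a minimum -log10 q of 5.0 LHX6 and ARX were in place 2.

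**Figure D1:**
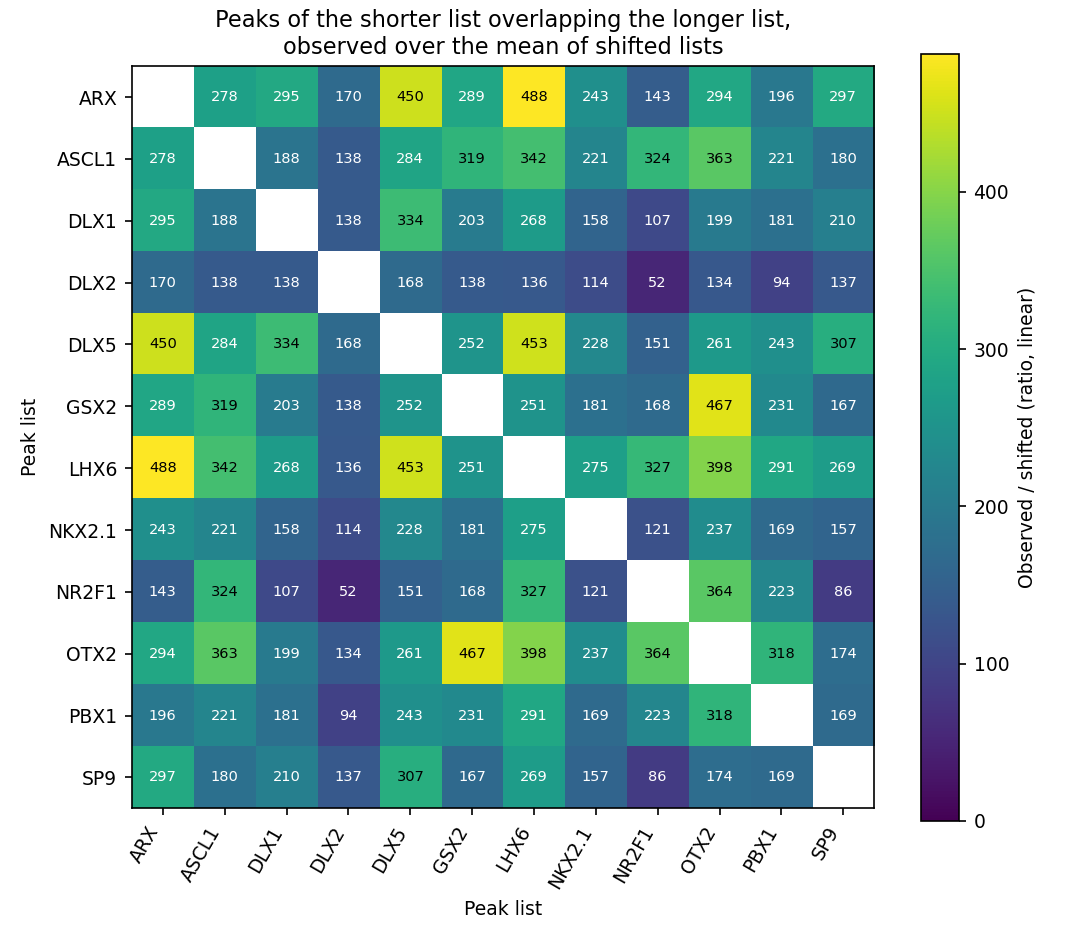
Enrichment of overlap for each pair of the 12 peak lists, as the number of peaks of the shorter list overlapping the longer list over the mean of 100 circular shifts (linear color scale and printed ratio). LHX6 with ARX is highest at 488 and NR2F1 with DLX2 lowest at 51.7.

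Merging overlapping peaks showed how many factors had a peak in each region, and highly shared regions lay at the genes of the DLX family. Between Dlx6 and Dlx5, a region on chromosome 6 from 6868964 to 6870235 (mm10) held 11 factors, all except NR2F1. The regions from 6861315 to 6863151, beside Dlx6, and from 6871462 to 6872629 held 8 factors each. Between Dlx1 and Dlx2, chromosome 2 from 71534762 to 71536752 held 10 factors and 71537317 to 71538752 held 9. A region over a boundary of Dlx1, 71527412 to 71528738, held 8. All of these lay in bins with H3K4me3 contacts.

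**Figure D2:**
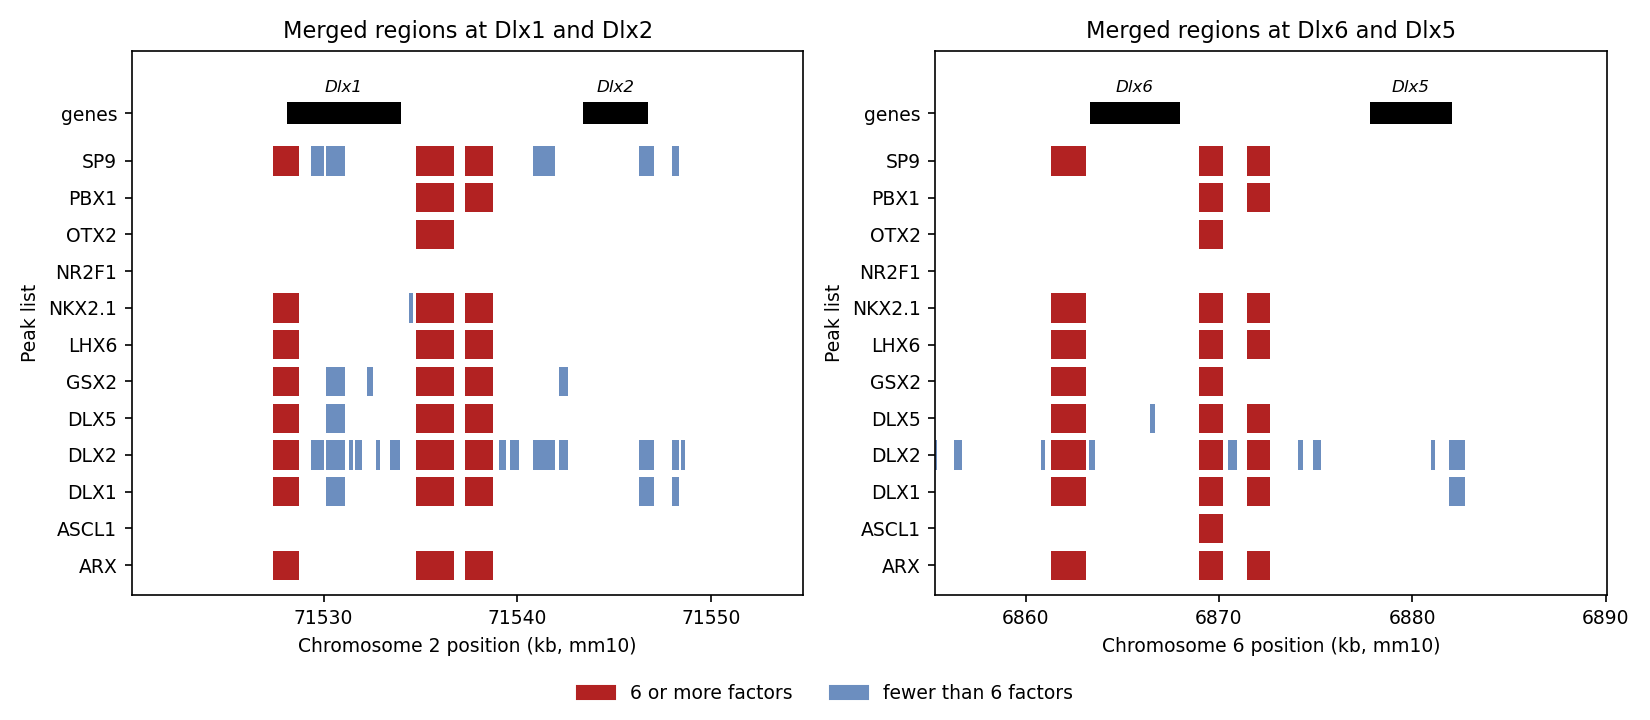
Merged regions at Dlx1 and Dlx2 (chromosome 2) and at Dlx6 and Dlx5 (chromosome 6) by position in kb (mm10), with a bar in each list that has a peak in the region, drawn to the extent of the merged region, and black bars for genes. Red bars mark regions of 6 or more factors, up to 11 between Dlx6 and Dlx5 and 10 between Dlx1 and Dlx2.

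The lists gave 28256 regions, of which 16441 (58.2%) held 1 factor and 1994 (7.06%) held 6 or more. With every list shifted independently, no region of 5 or more factors arose in 100 shifts. LHX6 had 55.3% of its peaks in regions of 6 or more factors (exact 95% interval 52.9 to 57.6), ARX 45.9% (44.4 to 47.4), DLX5 43.8% (42.4 to 45.3) and OTX2 43.0% (40.8 to 45.1). With a limit of 8 factors the order changed, to 35.7% for LHX6, 30.9% for OTX2, 27.4% for ASCL1, 23.2% for ARX and 21.5% for DLX5. This order counts hotspot peaks, which made up 11.9% of ASCL1 peaks, 10.2% of LHX6, 9.80% of OTX2, 5.25% of ARX and 4.52% of DLX5. It was not computed without hotspots, so it need not reflect shared binding. DLX2 had 11.9% of its peaks (11.5 to 12.4) in regions of 6 or more factors but was present at 98.5% of these regions. SP9 was present at 90.8% of them, DLX5 at 89.3%, ARX at 87.5%, DLX1 at 86.6% and NR2F1 at 7.62%, or 3.87% without hotspots, which also took its peaks in such regions from 22.0% to 11.1%. NR2F1 had 63.0% of its peaks (59.7 to 66.2) in regions with no other factor, DLX2 38.1% (37.3 to 38.8), NKX2.1 33.8% (32.7 to 35.0) and PBX1 33.6% (32.1 to 35.2), against 7.94% (7.14 to 8.79) for ARX and 8.86% (8.04 to 9.73) for DLX5.

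The enrichment near gene boundaries was absent from highly shared regions. Of the regions with 6 or more factors, 97.5% had their summit more than 1000 bp from a boundary, near the 96.9% of shifted regions, and the boundary share of 2.46% (1.82 to 3.24) included the shifted mean of 3.07% in its interval. At 1 factor the share was 19.2% (18.6 to 19.8), 6.23 times that of shifted regions. The 61 regions in all 12 lists included the 10 ranked highest: 4 on chromosome 2 between 98662099 and 98667454 with no gene within 100 kb, 4 on chromosome 9 (35305062 to 35305659 near Rpusd4, 3025302 to 3026063, 3029992 to 3030421, and 24541866 to 24542290 near Dpy19l2), 1 on chromosome 15 from 75085387 to 75087191 near Ly6c2, and 1 inside Aida on chromosome 1 from 183298989 to 183299707. Across these 61 regions the fold enrichment of any 2 lists had a median Spearman rho of 0.883, against 0.112 across regions of 6 to 10 lists; regions are not independent replicates. Outside their 20 kb surroundings, a choice made after the values were seen, the highest-ranked regions held 11 factors. The first 4 were chromosome 11 from 54140432 to 54140837 near P4ha2, chromosome 6 from 3201312 to 3201688 with no gene within 100 kb and outside contact bins, chromosome 7 from 109190966 to 109192272 near Lmo1, a LIM-only cofactor gene, and chromosome 19 from 59043124 to 59044936 inside Shtn1, which encodes the neurite outgrowth protein shootin. Leaving out these surroundings removes only regions near those that all 12 lists hold, so similar regions that 1 list missed may remain. The first 2 of these 4, 406 and 377 bp wide, held NR2F1, and the Lmo1 and Shtn1 regions (1307 and 1813 bp) did not. NR2F1 was in 48.7% of all regions of 11 factors, hotspots included, against 1.74% at 8. Whether the first 2 reflect binding was not tested. The count of 1994 became 1322 without the DLX2 list, 1250 with a minimum -log10 q of 5.0 and 287 with the 865 most significant peaks per list.

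**Figure D3:**
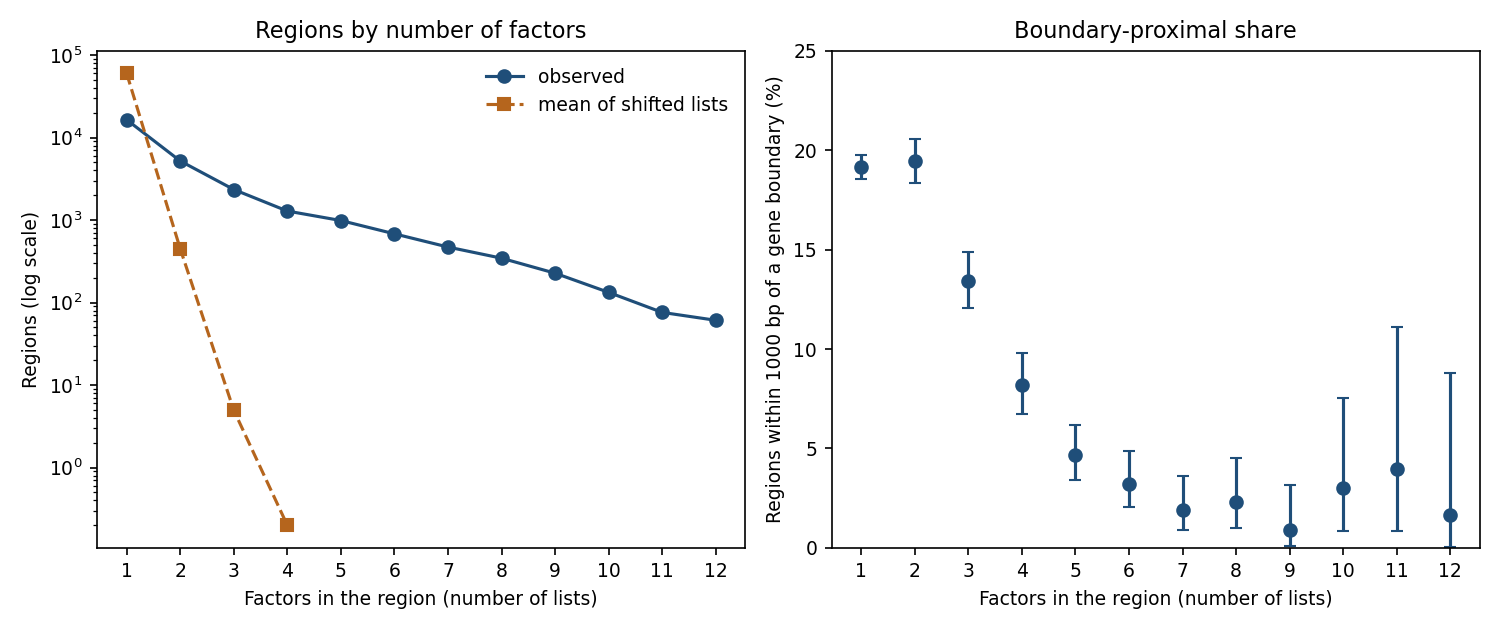
Left, number of merged regions (log scale) by number of factors, observed (circles) and as the mean of 100 independent shifts of every list (squares, absent where the mean was 0). Right, percent of regions with a summit within 1000 bp of a gene boundary, with exact binomial 95% intervals as bars: 19.2% at 1 factor and 1.64% at 12.

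The contact list asked whether bound regions lie in bins that contact other bins through H3K4me3. Zfp608, which encodes a zinc finger protein, was linked by contacts from the bins of its boundaries to 13 distal regions of 6 or more factors, the most of any gene. The coregulator gene Mn1 followed with 9, then Sox11, a SoxC gene of postmitotic neurons, with 8, and the progenitor gene Sox2 and the GABA synthesis gene Gad1 with 7 each. Setbp1 and Pitpnb, which lies beside Mn1, had 6 each. Cdca7, Sox4, Id4, Hoxa13, the TALE homeobox genes Pbx3 and Meis2, and Erich2, which lies beside Gad1, had 5 each. Zfp703, Btg1, the neural POU gene Pou3f3, Tox3, Sp9 and the striatal gene Zfp503 had 4 each. These counts were not adjusted for the number of contacts of a gene, which was 52 for Zfp608, 116 for Sox11 and 23 for Erich2. Hoxa13 and Erich2 had no region assigned by position.

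The list held 113048 contacts between 56951 bins of 10 kb on 19 chromosomes. Their median distance was 350 kb, the median count was 21 and the median of observed over expected count was 3.46. Among autosomal regions of 6 or more factors, 53.8% (exact 95% interval 51.6 to 56.0) lay in a contact bin, 2.30 times the share of shifted regions. For regions with 1 factor the share was 47.3% (46.5 to 48.0) and the ratio 2.01. It was 71.0% (62.4 to 78.6) at 10 factors, 42.5% at 11 (31 of 73 regions) and 15.8% (7.48 to 27.9) at 12, where the ratio was 0.6. Among single lists, ASCL1 had 60.4% of its peaks in contact bins (ratio 2.50) and LHX6 36.0% (ratio 1.54). The contacts pooled several runs into 1 list, and their bins of 10 kb can hold several genes and regions.

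**Figure D4:**
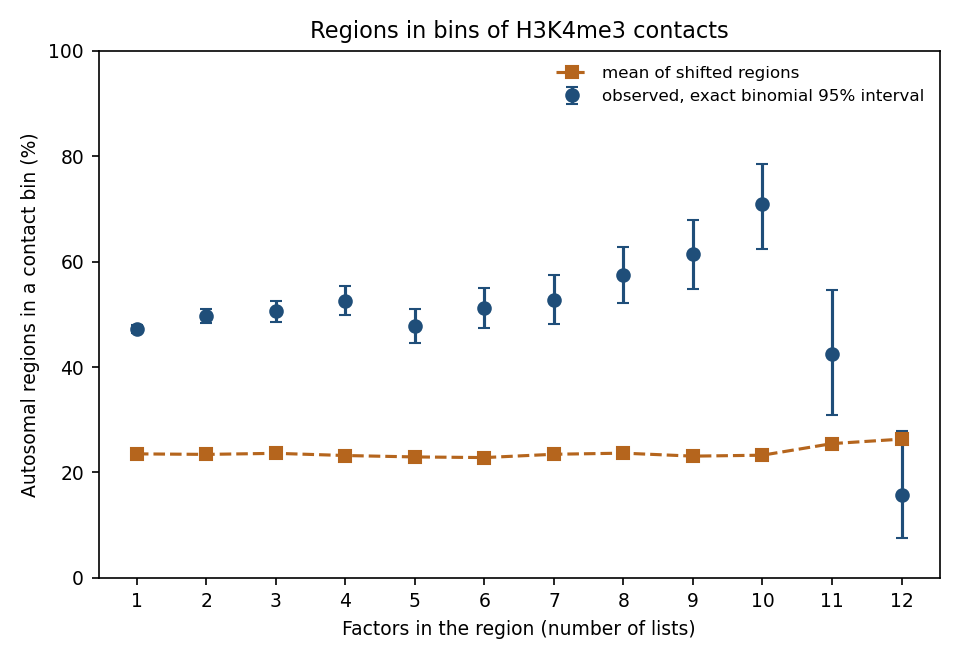
Percent of autosomal regions lying in a bin of an H3K4me3 contact by number of factors (circles, bars are exact binomial 95% intervals) and the mean of 100 circular shifts (squares). The share is 71.0% at 10 factors and 15.8% at 12.

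Contacts also joined bound regions with each other. Bins with a region of 6 or more factors faced another such bin in 285 contacts, against a mean of 133.6 when far bins were permuted among contacts of the same distance, a ratio of 2.13. By the cluster types in the contact list, 62.1% of contacts were SharpPeak, 32.4% BroadPeak and 5.48% Singleton. The permutation moved each contact on its own and did not keep clusters together. Contacts of 1 cluster thus counted as separate, and the permuted ranges may be too narrow. For LHX6 the ratio of contacts with a peak in both bins was 2.20, with 65 contacts, for OTX2 1.83, for ARX 1.71, for DLX5 1.53 and for GSX2 1.52. For DLX2 it was 1.02 and for NKX2.1 1.11, with 5560 and 1100 contacts, and for any factor 0.948; the DLX2 count lay below the permuted maximum of 5628. The pair of ARX and LHX6 at opposite bins had a ratio of 1.64 with 282 contacts, and DLX2 with NKX2.1 had 0.976. The ratio for NR2F1 rested on 17 contacts, within the permuted range that reached 23. Against the bin at the same distance on the other side, which need not take part in any contact, the ratio was 5.26 for 6 or more factors, 2.61 for DLX2, 2.74 for NKX2.1 and 2.09 for any factor. With these bins limited to those in another contact and weighted to as many contacts as the partners have, it was 2.11 (95% interval over resampled chromosomes 1.22 to 3.81), 1.18 (1.09 to 1.26), 1.22 (1.08 to 1.35) and 1.07 (1.01 to 1.11). The weighted ratio was 2.11 (1.28 to 3.81) for OTX2, 1.58 (1.23 to 1.94) for GSX2 and 1.50 (1.26 to 1.87) for DLX5. For LHX6 (1.51, 0.873 to 4.94) and ARX (1.18, 0.926 to 1.37) the interval included no enrichment, so the order of lists differed from that by permutation.

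Gene lists fixed before the data were examined were set against random lists by the factors in their assigned regions. The random lists were matched on gene territory but not on expression or open chromatin, so a high mean need not be particular to a programme. Genes of GABAergic identity had a mean of 6.67 factors in their assigned regions, against 1.19 in random lists, and all 12 had at least 1 region. Dlx6 had 11 factors, Dlx1 and the GABA synthesis gene Gad2 10 each, and Sp9 9. LGE and striatal genes had a mean of 5.00 against 2.55, with 11 factors at Pbx3 and at the forkhead genes Foxp1 and Foxp2 and 10 at Meis2. The genes Drd1, Penk and Ppp1r1b of mature striatal neurons had no region. MGE genes had a mean of 5.78 against 2.62, with 11 factors at Zeb2 and Nkx2-1 and 10 at Sox6 and Erbb4, a neuregulin receptor gene, and none at Gbx1, Gbx2 and Shh. CGE genes had a mean of 4.42 against 2.11, with 7 factors each at Adarb2, Htr3a, Npas1 and Reln and none at Vip. Genes with none lacked regions assigned by position only. By contacts, linked regions held 10 factors for Gbx2, 8 for Drd1, 4 for Shh and 1 for Ppp1r1b, and none for Gbx1, Penk and Vip.

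Ventricular zone progenitor genes had a mean of 5.00 against 1.53 in random lists, with 10 factors at Ascl1 and Notch1, 9 at Sox2, 8 at the glutamate transporter gene Slc1a3 and none at Ccnd1. Notch signalling genes had 4.77 against 1.46, with 8 factors at the ligand gene Dll1, 7 at Notch2, 6 at the target gene Hes5 and none at Notch3. Migration and guidance genes had 8.00 against 3.69, the highest mean of the lists, with 11 factors at Robo1 and Nrp1 and 10 at Epha4. Cortical glutamatergic genes had 3.62 against 1.62, with 10 factors at Cux2, 8 at Lhx2 and Fezf2, 7 at Emx2 and none at Emx1 and Slc17a7. Pan-neuronal genes had 6.18 against 2.99, with 10 factors at Elavl4, 9 at Syt1 and 8 at Map2 and Rbfox3. Oligodendrocyte genes had 3.50 against 1.32, with 8 factors at Pdgfra, 6 at Olig1, 5 at Nkx2-2, 3 at Olig2 and none at Plp1.

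The other lists held genes outside these programmes. Housekeeping genes had a mean of 2.25 factors against 0.546 (percentile 99.975), with 5 at Psmb2, 4 at Polr2a, 3 at Ubc and Ppia and none at Hprt and Rps18. Choroid plexus genes had 2.33 against 1.17 (percentile 91.8 of random lists), with 9 at Otx2, 3 at Kl, 1 each at Clic6 and Ttr and none at Aqp1 and Folr1. The list of microglia, endothelium and blood had 1.44 against 1.32 (percentile 62.4), with 9 at Pecam1, 7 at Cdh5, 2 at C1qa and Kdr and none at Aif1, Cldn5, Csf1r, Cx3cr1, Gata1, Hba-a1, Hbb-bs, Klf1 and Tmem119. Liver and muscle genes had 0.333 against 0.644 (percentile 22.7), with 4 factors at Apoa2 and none at Acta1, Afp, Alb, Apoa1, Ckm, Cyp3a11, Fgb, Myh3, Myod1, Myog and Tnnt3.

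Of the 15 lists, 12 lay above the 95th percentile of 10000 random lists by factors, and 12 by distal regions, where choroid plexus genes passed (98.2) and housekeeping genes did not (84.5). Single genes carried some calls by distal regions: without Otx2, itself the gene of a profiled factor, choroid plexus genes had a percentile of 79.2, and pan-neuronal genes fell from 96.6 to 93.7 without Map2, 94.3 without Syt1 and 94.7 without Elavl4. A percentile describes these libraries and is not a p-value. By factor, 98 of the 180 combinations of list and factor lay above the 95th percentile, against 9 expected for random lists. The combinations share genes and regions and are not independent. ASCL1 had a region at 8 of 13 Notch genes, 11.3 times the random share, and at 7 of 11 pan-neuronal genes. LHX6 was at 10 of 18 MGE genes (55.6%), 5.40 times the random share of 10.3%. It was at 41.7% of GABAergic identity genes (14.7 times) and 58.3% of profiled factor genes (12.6 times). The random shares of those 2 lists were lower, 2.8% and 4.6%, so the ratios do not rank the lists. OTX2 was at 9 of 18 progenitor genes (8.31 times). GSX2 was at 9 of 16 cortical genes (4.49 times) and SP9 at 12 of 13 migration genes (2.03 times). By contacts, distal regions of 6 or more factors linked to GABAergic genes averaged 2.17 against 0.380 in random lists (percentile 99.98) and to LGE genes 1.36 against 0.241 (percentile 100), but to MGE genes 0.500 against 0.290 (percentile 87.2). Some calls changed: without matching, housekeeping genes had a percentile of 92.8 by factors instead of 99.975 and choroid plexus genes 93.2 by distal regions. With all regions within 100 kb counted, choroid plexus genes had 98.7 by factors, and with a minimum -log10 q of 5.0 pan-neuronal genes had 94.6 by distal regions.

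**Figure D5:**
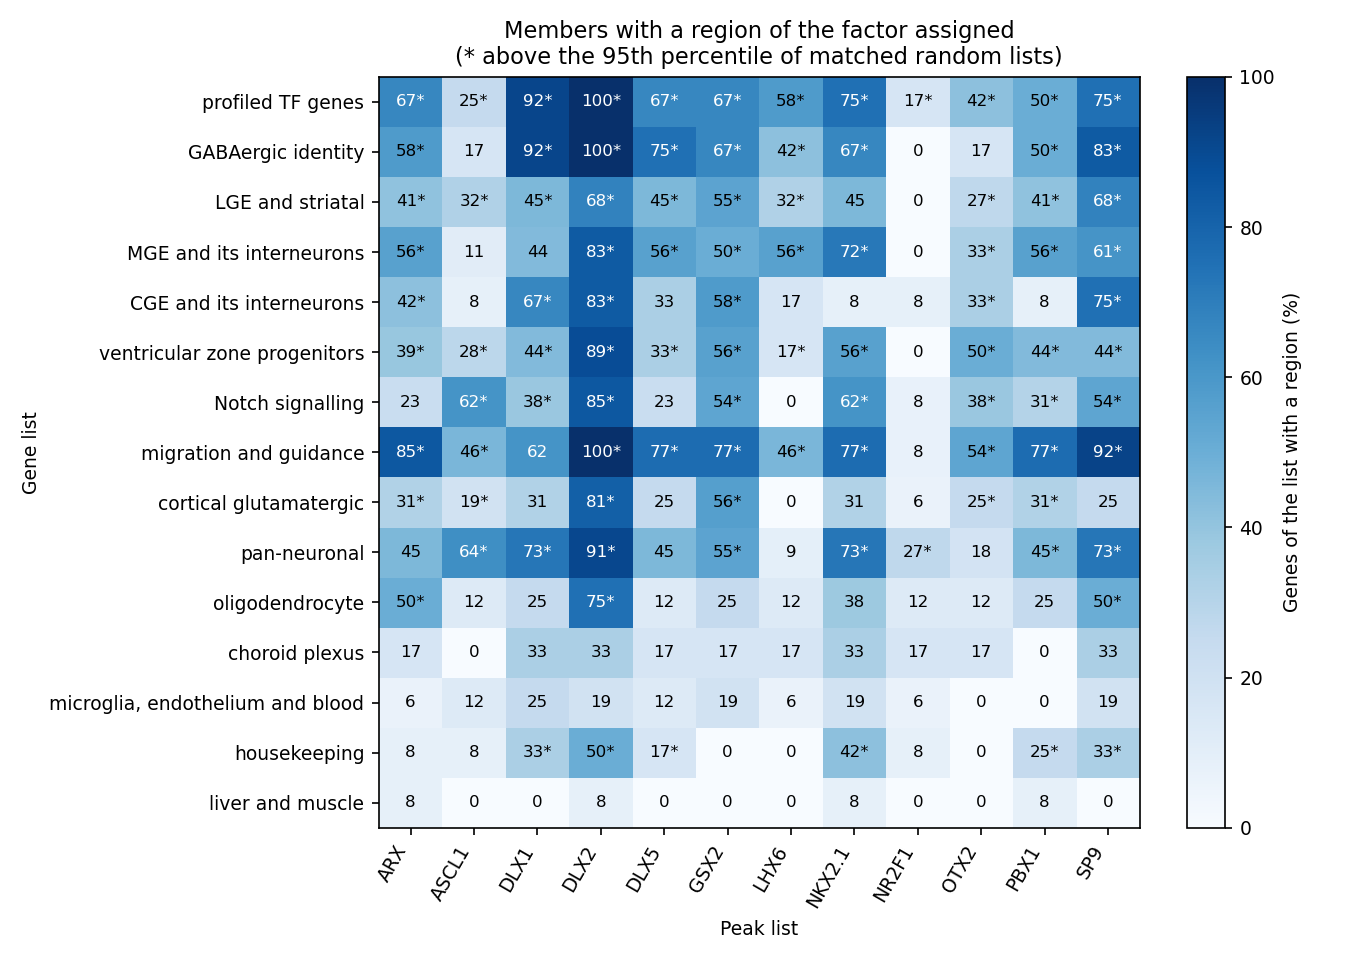
Percent of the genes of each list (rows) that have a region of each factor (columns) assigned, with an asterisk where the value lies above the 95th percentile of matched random lists. DLX2 has a region at 100% of GABAergic genes, and ASCL1 at 61.5% of Notch genes.

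The profiled factors were found at each other's genes. Pbx1 (chromosome 1, 168119364 to 168432365, mm10) had 73 peaks of 11 factors, and Nkx2-1 (chromosome 12, 56531935 to 56536908) had 46 peaks of 11 factors. Dlx1 and Ascl1 had 10 factors each, Otx2 and Sp9 9, Lhx6 8, Dlx2 7 and Gsx2 6, of which GSX2 itself had 7 peaks. Nr2f1 had 4 factors, Dlx5 had 2 and Arx had DLX2 alone with 3 peaks. NKX2.1 had 10 peaks at its own gene and 2 at Lhx6. LHX6 had 3 peaks assigned to Nkx2-1, in regions 60679, 73001 and 90606 bp from the gene.

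DLX2 had peaks at all 12 genes, DLX1 at 11, NKX2.1 and SP9 at 9 and NR2F1 at 2. Peaks were found in 88 of the 144 combinations of factor and gene (61.1%), against 12.6% in matched random sets, above all 10000 sets. A factor had a peak at its own gene in 9 of 12 cases, the others being ARX, ASCL1 and DLX5. Besides the region of 10 factors beside Dlx1, another of 10 factors lay on chromosome 12 from 56458491 to 56459266, 73001 bp from Nkx2-1. Regions of 9 factors included chromosome 2 from 73267835 to 73269528, beside Sp9, and chromosome 10 from 87446591 to 87448244, 43937 bp from Ascl1. By contacts, regions linked to Sp9, Dlx1 and Dlx2 held 11 factors, and Arx on the X chromosome had no contacts because the list covers autosomes. With every region within 100 kb counted, Arx and Nr2f1 had 10 factors and Dlx2, Dlx5 and Gsx2 11, so low counts at these genes depended on assigning a region to the nearest gene. Within 50 kb Nkx2-1 had 5 factors, with a minimum -log10 q of 5.0 Lhx6 had 5, and with the 865 most significant peaks per list 30.6% of combinations had a peak against 2.99% at random.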

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

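Alternatives that left out hotspots, the surroundings of wide peaks or single genes of a list, and the bin on the other side as a chance level, were chosen after seeing the data; the others were fixed earlier. No paired analysis was possible because each factor had 1 library. The 4 alternatives of the motif search were not run, since they need the genome sequence, which was not used here. Depth limits how weak a called peak can be, and with 10557366 (ARX) to 41224665 (PBX1) tags kept per library, a missing peak does not show absent binding.

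The total of 60950 peaks became 40592 with a minimum fold of 5.0, by construction. The boundary share over all lists, 11.9%, was 9.75% within 500 bp and 15.7% within 2500 bp, by construction of the distance, 8.90% with equal numbers of top peaks and 12.2% without hotspots. The median pair ratio of 222 was 330.1 with an overlap of at least 50% of the shorter peak, 318 for summits within 200 bp, 473.7 with equal numbers of top peaks, 264 for distal peaks only and 259.6 with a -log10 q of at least 5.0. The number of regions with 6 or more factors, 1994, was 1250 with that q and 287 with equal numbers of top peaks. Leaving out each list in turn gave 1322 (without DLX2) to 1981 (without NR2F1), fewer by construction since the limit of 6 stayed. The distal share of highly shared regions, 97.5%, was 95.3% with a limit of 4 factors. The contact ratio of 2.30 was 2.65 with stricter contacts and 2.41 without hotspots, and the odds against regions with 1 factor were 1.30. The ratio for contacts joining highly shared regions, 2.13, was 5.26 against the bin on the other side. The share of profiled factors at each other's genes, 61.1%, was 30.6% with equal numbers of top peaks, against 2.99% in random sets, and still above all random sets. Except where the construction gives the reason, the cause was not tested.

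With equal numbers of top peaks, the enrichment near gene boundaries was lost for DLX2, from 4.85 to 0.784 (not distinguishable from 1), and reversed for SP9, from 5.46 to 0.516; the cause was not tested. Among the other values for separate lists, factors and genes, 676 stayed within their interval or side of the limit, 79 moved, 9 lost their call and 7 gained one.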

Other observations

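The test of fold enrichment across regions in all lists and the test of contact-prone bins were set out before their results were seen; the tests of contact bins at those regions, of top peaks, of sharing near boundaries and of bins in as many contacts were chosen only after the result was seen.

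Exact combinations of factors outside hotspots were dominated by DLX2 with a partner. DLX2 with SP9 alone formed 1095 regions, DLX1 with DLX2 829, DLX2 with NKX2.1 680 and DLX2 with GSX2 555. The most frequent combination of 5 factors was ARX, DLX1, DLX2, DLX5 and SP9, with 234 regions, of which 232 lay away from gene boundaries. With LHX6 and NKX2.1 added, it formed 106 regions. NKX2.1 with PBX1 alone formed 144 regions, of which 100 lay near a gene boundary. DLX2, GSX2 and OTX2 formed 158 regions, with 156 of them away from boundaries.

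Of the 180 combinations of list and factor, 0 lay below the 5th percentile of random lists. Many combinations could not have reached it, because the lists are short. PBX1, absent from all genes of microglia, endothelium and blood, had a percentile of 9.2, and LHX6, absent from all housekeeping genes, had 46.5. The count therefore cannot show whether a list lacked a factor. LHX6 had no region at the 16 cortical glutamatergic genes or the 13 Notch genes, which random lists of this size often miss too (percentiles 20.2 and 27.2). The peaks of DLX2 in regions of 6 or more factors had a median fold of 15.4, against 4.91 for its peaks alone, and SP9 had 8.41 against 4.75, per the authors' deposited values. DLX1 had 7.22 against 6.87.

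The 61 regions in all 12 lists, in 39 loci more than 1 Mb apart, might be read pile-ups that do not depend on the antibody. Fold enrichment across these regions rose and fell together in any pair of lists, with a median rho of 0.883 (0.663 to 0.967), against 0.112 across regions of 6 to 10 lists. Shared enhancers or promoters that lie in H3K4me3 contacts as often as regions of 6 to 10 lists were argued against. Of the 37 autosomal loci of the regions in all 12 lists, 21.6% (exact 95% interval 9.83 to 38.2, highest of 100 shifts 45.9) had a region in a contact bin. The share was 54.8% (52.3 to 57.2) for the loci of regions of 6 to 10 lists. The test cannot decide on shared elements outside such contacts, or at loci where contact reads could not be placed. Pile-ups stay open as a candidate explanation, which the tags of the inputs could decide. Some lists come from other series, per the design text, and all 12 hold these regions.

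The share of peaks near gene boundaries differed between lists, and weak peaks were a candidate explanation. For NKX2.1 and PBX1 they were argued against as the whole account. At least 10.5% (exact 95% interval 8.56 to 12.8, NKX2.1) of their top 865 peaks lay near boundaries, although weaker peaks raised the share of NKX2.1 to 17.1%. For ASCL1 the share of top peaks was 15.3% (12.9 to 17.8). These were 865 of its 1540 peaks, most of the list, so they decide little about its weak peaks. For DLX2 and SP9 weak peaks stay open, with at most 2.43% of top peaks near boundaries, and for NR2F1, which has 865 peaks in all, top peaks decide nothing. A common signal at the same promoters as the whole account was taken to make boundary peaks the more shared ones. Each kind of peak was asked from the list with fewer of that kind. Boundary peaks overlapped more often than distal peaks in 5 of 66 pairs, with medians of 29.3% and 38.0%. Distal peaks were widely shared too, so this comparison cannot exclude a common signal at some promoters. Antibody and fixation differ with the factor and were not tested.

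Contacts joined highly shared regions with each other. Partner bins held such a region 3.76 times as often as bins at the same distance on the other side that take part in another contact (278 against 74 of 3444), which argues against taking part in contacts as the whole account. The partners took part in a median of 9 contacts and the other bins in 3, and weighted to as many contacts the ratio was 2.11 (95% interval over resampled chromosomes 1.22 to 3.81). Over 6 groupings by number of contacts the lower bound ranged from 1.19 to 1.30, around the limit of 1.2, so closeness among bins with many contacts stays open as a candidate explanation. The compartment or domain they share was not tested.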
